A study of Homo sapiens with 3 samples.

How the data were processed

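The RNA was total RNA from A2780 cells with the pBABE vector (1 library) or exogenous miR-181a (2 libraries), enriched for poly-A RNA with oligo(dT) beads and sequenced on an Illumina instrument, per the labels' protocols. The authors mapped reads to the human genome hg19, took a density profile in sliding windows of 50 bp along each gene and kept the median of the profile as the coverage of the gene, per the labels' protocols. The aligner and the annotation release are not given in the sources used here. The protocols also name a log transformation and quantile normalization, but the deposited coverage signal is on a linear scale and its quantiles differ between the 3 columns, so no common scaling was assumed. The authors' deposited ratio, signed fold and log columns recomputed from the coverage columns in 100% of numeric cells, to a relative difference of 0.000001, and were not used further.

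The table has 29156 rows, 1 per RefSeq transcript, for 18877 symbols. Symbols turned into dates by a spreadsheet (54 rows) were restored by accession. The vector value is blank in 308 rows, of which 204 are above 0 in both pools, and these rows were left out, which leaves 28848 rows and 18674 genes. Where a symbol had several rows, as 5775 genes did, the row with the highest mean over the 3 libraries was used. A median over windows is 0 when fewer than 50% of windows are covered, so a gene listed at 0 may still have reads. The deposited table holds no counts, so the depth is unknown and no counting interval is given.

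Values were taken as log2(coverage + 1). Genes with a mean above the lowest 25% of those not at 0 in all 3 libraries were tested (12552 genes) with limma 3.58.1 in R 4.3.3, the 2 miR-181a libraries against the vector library, with eBayes, a variance trend and the Benjamini-Hochberg adjustment at 0.05. The test has 1 residual degree of freedom, between the pools, so the lone vector library is assumed to vary as the pools do. A size rule of at least 1 log2 unit in the same direction in both pools was counted beside it. Checked on simulated data of 12552 genes for this comparison, the fit called 96% of 50 genes raised by 1 log2 unit, 70% of 50 lowered by 1, all 50 at each of 2 and -2, and 31 of 12352 unchanged genes. Only genes of higher coverage were changed there, the offset between the pools was taken out, and no excess was added to the vector library. These shares therefore do not carry over to the data, where 57 of the 318 genes past the size rule upward passed the test.

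Gene lists, 25 in all, were tested with camera at a preset correlation of 0.01 over the 23 lists with at least 5 tested genes, then with an estimated correlation, and each list median was placed among 10000 random lists matched on mean expression. By fry, which tests whether a list moves on balance one way, epithelial, endothelial, ovarian lineage, and neural and germ line markers passed, each down with an adjusted p of 0.0323. Of their tested members, 7 of 16, 3 of 7, 3 of 7 and 5 of 11 were at 0 in both pools. Such genes pass the filter only through their vector value, so fry cannot tell these falls from an effect of the filter. Unchanged pools were simulated 20 times with the spread seen between the pools, without and with a vector value drawn from transcripts at 0 in both pools added to each transcript of the vector library. In a further simulation, chosen after the data were examined, the vector value was a mixture of a transcript's own coverage and that of another. The share of the other, 0.29, was the median ratio of 9 percentiles of the vector values of silent transcripts to those of the pool mean. The pools were set apart by the median difference between them in genes above 50. Seed matches of miR-181a-5p were counted in the 3 prime UTR of 1 transcript per gene from GENCODE annotation on GRCh37, the same assembly as hg19, and 12329 of the 12552 tested genes (98.2%) were matched, 12272 of them with a 3 prime UTR. Each 7-mer was compared with others found in a number of genes within 25% of its own and in at least 50 genes. Coordinates are gene spans from the same annotation.

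Choices were fixed before the data were examined, among them the rule for named genes. It takes the 10 highest and 10 lowest by mean log2 fold among genes past the test and the size rule, the 5 farthest in each direction between pools, SMAD7, mir-181 precursors and host genes, and in each list up to 4 members with the largest fold shared by both pools and any member past the test, of which the text gives examples. Alternatives covered the filter, scaling, pseudocount, choice of row, variance model, each pool left out, the size threshold and the intergene correlation. Chosen after the data were examined were the row picked without the vector value, genes above 0 in both pools, the size rule in every row, a limit on the vector excess, the 2 shifts by the median ratio of genes above 50, by the mean over the 3 libraries or over the pools, and 7-mers of the same base composition. A count model and unnormalized values were planned for a file that held them and were not run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.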

Results

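RNA sequencing measured messenger RNA in A2780, a line derived from an undifferentiated ovarian tumour, in 3 libraries. The control cells carried the empty pBABE retroviral vector (1 library), and 2 pools of cells expressed exogenous miR-181a (1 library each, called pool 1 and pool 2 here). The labels call the miR-181a cells polyclonal pools in one place and clones in another and say nothing more about how far the pools are independent cultures, so p-values measure the spread between these 2 libraries, which may be partly technical. The deposited values are coverage per RefSeq transcript, and no read counts are given with them, so the depth of each library is unknown. Over the 28848 transcripts used, coverage summed to 798228 in the vector library, 907092 in pool 1 and 719263 in pool 2, and 12.8%, 32.3% and 32.2% of transcripts were listed at 0. Transcripts listed at 0 in both pools numbered 8822, and 5549 of them (62.9%) had a value above 0 in the vector library, with a median of 1.15 over all 8822 and a 99th percentile of 121. From the 60th to the 99.9th percentile, these vector values were 0.25 to 0.35 times the same percentile of the pool mean over all transcripts. This property of the vector library bears on every gene reported as lower below. Folds are differences of log2(coverage + 1), which understates the change of genes of low coverage.

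The title of the series asks which genes miR-181a acts on, so SMAD7, an inhibitor of TGF-beta signalling that is a reported miR-181a target, was examined first. SMAD7 (NM_005904, chromosome 18, 46446223 to 46477335 on GRCh37, protein coding) had a coverage of 58.0 in the vector library and 1.72 ± 0.22 (SD, n = 2) in the pools. Its log2 fold was -4.44 (SE 0.19), past the limma test with an adjusted p of 0.0067 and lower in both pools. A vector value as far above the pools as that of SMAD7 was found in 2.38% of transcripts listed at 0 in both pools, and SMAD7 has a single transcript in the table. The level of miR-181a itself was not analysed here, since the table used names no mir-181 precursor. NR6A1, which spans the mir-181 locus of chromosome 9 on the opposite strand and so does not report on the precursor, had a coverage of 54.5 in the vector library and 10.0 ± 2.35 (SD, n = 2) in the pools and did not pass the test (limma adjusted p = 0.07).

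Genes that rose with miR-181a included CDH2, SPOCK2 and CENPF. CDH2, which encodes the adhesion protein N-cadherin (chromosome 18, 25512843 to 25757910), went from 7.02 in the vector library to 45.6 ± 8.34 (SD, n = 2) in the pools, a log2 fold of 2.53 (SE 0.31, limma adjusted p = 0.047). SPOCK2, a proteoglycan of the extracellular matrix (chromosome 10, 73818792 to 73848790), went from 10.2 to 189 ± 70.1 (SD, n = 2), the largest log2 fold among genes past both criteria at 4.03 (SE 0.48, limma adjusted p = 0.046). PPIC, a peptidyl-prolyl isomerase, went from 3.51 to 46.9, and SCN9A, a voltage-gated sodium channel, from 2.63 to 25.3. TDRD3, a Tudor domain protein, rose from 5.64 to 42.1, and MID1, a ubiquitin ligase bound to microtubules, rose from 0.48 to 8.66. The aldo-keto reductase gene AKR1C1 rose from 0.546 to 7.78. SPDYE3, ARSJ, an arylsulfatase, and FKBP7, another peptidyl-prolyl isomerase, completed the 10 genes with the highest folds, with log2 folds of 2.31, 2.30 and 2.29. Of 12 alternatives with a test, CDH2 and CENPF passed in 8 each and SPOCK2 in 7.

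**Figure D1:**
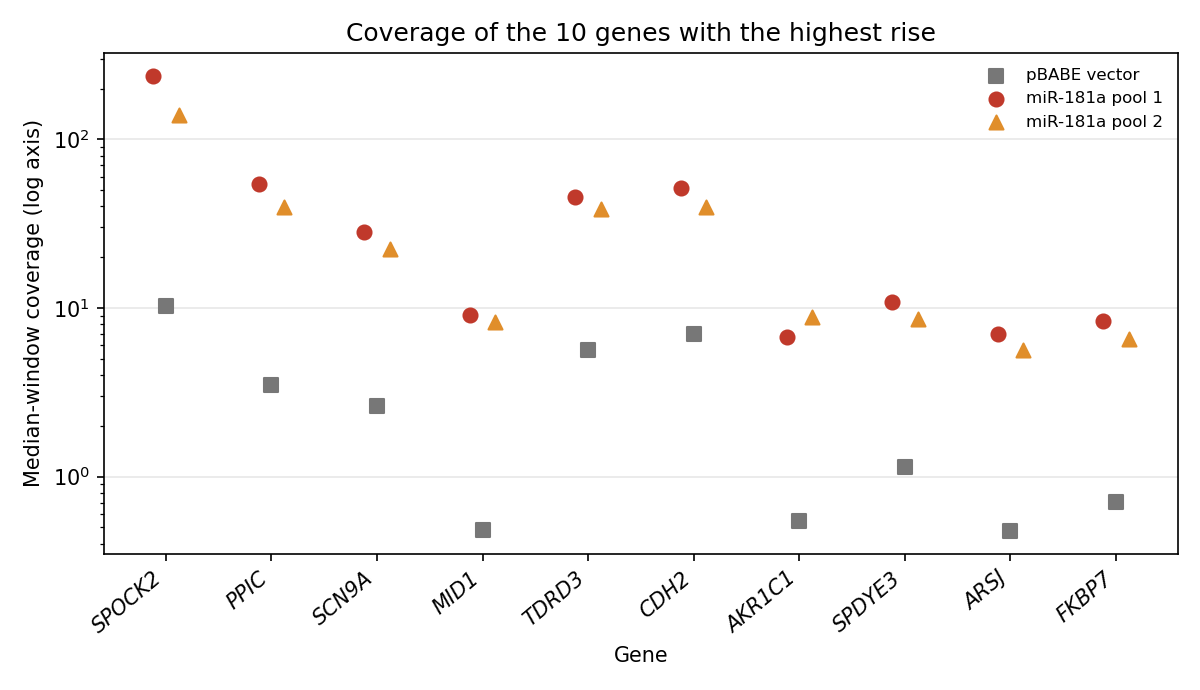
Coverage of the 10 genes with the highest log2 fold among those past the test and at least 1 log2 unit higher in both pools, with 1 point per library on a log axis. In each of the 10 genes both miR-181a pools lie above the vector library, as for CDH2 with 51.5 and 39.7 against 7.02.

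Of 12552 genes tested, 126 rose and 2725 fell by limma at an adjusted p of 0.05, and 318 genes were at least 1 log2 unit higher and 3430 at least 1 log2 unit lower in both pools. Both criteria held for 57 genes that rose and 2689 that fell. Counts of genes that rose or fell in the lists below are to be read beside 126 and 2725 of 12552. Of those 2725, 1535 were at 0 in both pools, where the filter fixed the fall. The share that fell in a list therefore also depends on how many of its members were at 0 in both pools. Libraries simulated as unchanged gave 0 to 3 genes higher and 0 to 2 lower by the size rule. When the excess seen in the vector library was added to them at random, they gave 0 to 2 genes higher and 3751 to 3927 lower. No difference in scale between the vector library and the pools was set in them. The 3430 lower genes observed were below their range, but after the 2 shifts described below 3978 and 4124 genes were lower, above it. The number of lower genes therefore cannot be placed against this simulation. The number of higher genes was above its range, also after the 2 shifts. When each vector value was instead made of 0.71 of its own coverage and 0.29 of that of another transcript drawn at random, 5 to 18 genes were higher and 3707 to 3826 lower. By the test these mixed libraries gave 19 to 38 genes that rose and 2689 to 2889 that fell, against the 126 and 2725 observed. The split of calls differed with scaling, which also takes the offset between the pools out of the spread that the test uses. The median log2 fold of the tested genes was 0.24 in pool 1 and -0.12 in pool 2 and was 0.64 and 0.30 in genes with a pool mean above 50 (0.57 and 0.24 at the median of the mixed libraries). With library medians set equal, the median fold was 0.49 and 6355 genes rose and 3701 fell. With each pool shifted by the median ratio of genes with a mean over the 3 libraries above 50 (0.55 and 0.21), an alternative chosen after seeing the data, 1039 rose and 5390 fell and 86 of the 318 genes stayed higher by the size rule. With the shift taken from genes with a pool mean above 50 (0.64 and 0.30), also chosen after seeing the data, 61 stayed higher.

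Genes that fell were led by transcripts that the pools list at 0. BHLHB9 on the X chromosome had the largest fall, from 3526 in the vector library to 2.09 ± 0.05 (SD, n = 2), but its 8 transcripts did not all meet the size rule. SPAM1, the sperm hyaluronidase, had a coverage of 727 in the vector library, and MX1, an interferon-induced GTPase, had 616, both listed at 0 in the pools. MX1 and SDR9C7, genes on different chromosomes, had the same vector value, as did FMR1NB and SGPP2. SDR9C7, TMEM63C, FMR1NB, SGPP2, C11orf63, C7orf29 and SDR42E1 had vector values from 616 down to 473 and were listed at 0 in both pools as well. Of the 2725 genes that fell, 1535 were listed at 0 in both pools, where the spread between the pools is 0 and the test is formal. A gene at 0 in both pools passes the filter only through its vector value. All 1535 such genes tested fell, so the filter fixed these falls in advance, also in the gene lists below. Of 1375 genes lower by the size rule with 2 or more distinct vector values, 420 met it in every transcript. Among genes named as lower here or below, MX1, SPINT1, DSP, MUC1, IRF7, BCL2L11, ENG, ATF3, PDPN, DDX4, PROM1, TCF7, DKK3 and EGR2 did not meet it in every transcript. PLAG1, named below as a gene that fell, did not meet the size rule even in the transcript used. Vector coverage more than 4 times the pool mean was found in 14.3% of transcripts with a pool mean of 1 to 10, 2.41% at 10 to 50 and 0.42% at 50 to 100, while pool 1 exceeded pool 2 by that factor in 0.42%, 0.01% and 0%.

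**Figure D2:**
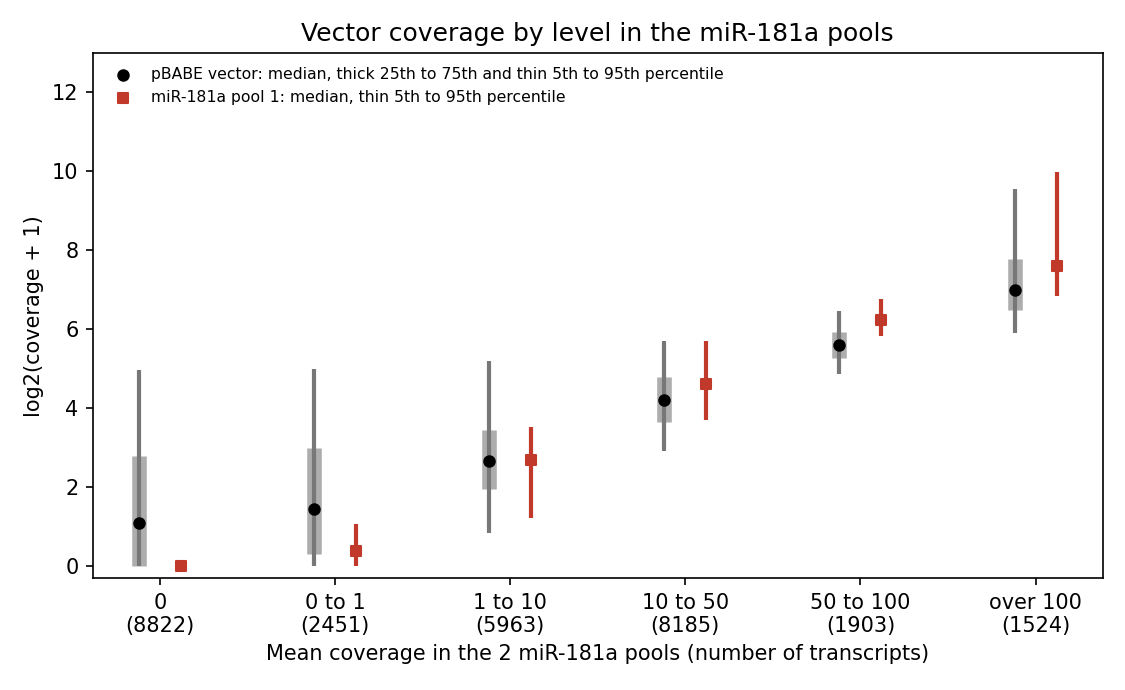
Vector and pool 1 coverage, as log2(coverage + 1), for transcripts binned by mean coverage in the 2 pools, with medians as points and percentiles as lines. Where both pools are at 0, the vector median is 1.15 and its 95th percentile 30.2 on the linear scale, and the upward spread shrinks as pool coverage rises to the bin of 50 to 100. In the bin over 100 it widens (median 126, 95th percentile 756), as does that of pool 1 (195 and 1005).

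Cholesterol biosynthesis genes stood higher in the pools as a group. Of the 24 measured, 22 were higher in both pools and 2 lower, and none passed the test singly, adjusted over all genes or adjusted over the list alone. The median log2 fold of the list was 0.84, at percentile 100 among 10000 random lists matched on expression, and camera with a preset correlation gave an adjusted p of 0.00125. Matching is on the mean over the 3 libraries here and below, unless the pool mean is named. With an estimated correlation no list of the 23 tested held, and the adjusted p was 0.966 for this one. That estimate rests on a single difference per gene, pool 2 minus pool 1, which leaned below 0 over all tested genes (median -0.27). Hardly any list could pass it, so here and below it cannot decide whether a list holds. SC4MOL, a sterol oxidase, went from 20.9 to 59.4 ± 2.21 (SD, n = 2), and EBP, a sterol isomerase, from 59.0 to 152 ± 7.21 (SD, n = 2). INSIG1, a regulator of sterol sensing, went from 18.5 to 44.6 ± 6.30 (SD, n = 2). The list's median stayed above 0 at 0.46 and 0.37 after the 2 shifts. The camera adjusted p was 0.0234 among genes above 0 in both pools, chosen after seeing the data, and 0.473 with a filter at the median.

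**Figure D3:**
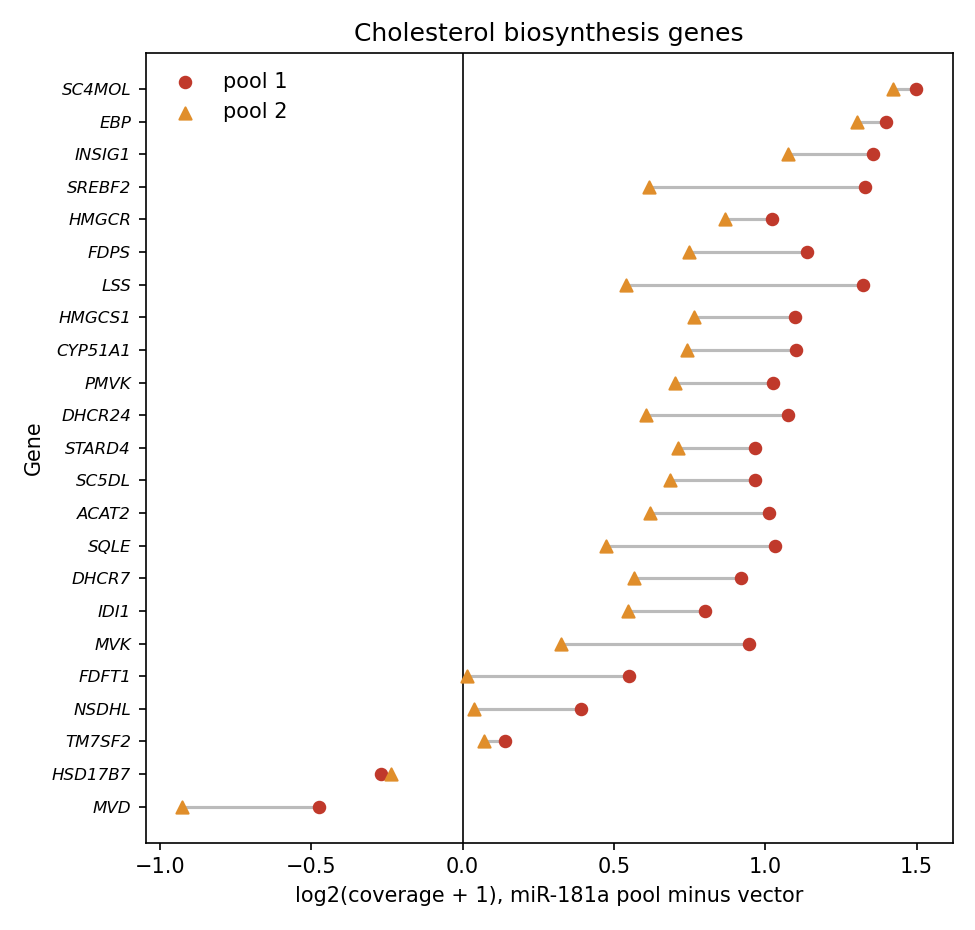
Difference in log2(coverage + 1) from the vector library for 23 of the 24 measured cholesterol biosynthesis genes, with 1 point for pool 1 and 1 for pool 2. The 2 genes to the left of 0, MVD and HSD17B7, are lower in both pools, and the other 21 shown are higher in both.

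Mitotic genes formed a second group that stood higher. Of 32 G2/M genes measured, 24 were higher in both pools, with a median log2 fold of 0.60 (percentile 99.6 among matched lists, camera adjusted p = 0.00169, and 0.966 with an estimated correlation), and the median was 0.21 and 0.12 after the 2 shifts. CENPF, a kinetochore protein, rose from 31.0 to 89.3 ± 4.67 (SD, n = 2), with a log2 fold of 1.5 (SE 0.18, limma adjusted p = 0.047). The proliferation marker MKI67 went from 11.9 to 31.1 and KIF20A, a mitotic kinesin, from 24.4 to 58.1, and neither passed the test. CENPA, the centromeric histone H3 variant, fell instead, from 274 to 17.8. Among 33 genes of G1/S and DNA replication, 22 were higher in both pools (median 0.51, and 0.13 and 0.04 after the 2 shifts, percentile 94.4 among matched lists, camera adjusted p = 0.00789, and 0.966 with an estimated correlation), and CCNE2, a cyclin of the G1/S transition, fell from 38.7 to 4.27. Of 29 genes of the unfolded protein response, 20 were higher in both pools (median 0.54, percentile 96.7 among matched lists, camera adjusted p = 0.015, and 0.966 with an estimated correlation). Their median was 0.16 and 0.07 after the 2 shifts, and the list no longer passed camera after the second (adjusted p = 0.0537). Matched on the pool mean, the percentile was 98.1 for G2/M, 85.3 for G1/S and 93.9 for the unfolded protein response. Among genes above 0 in both pools the G2/M, G1/S and unfolded protein response lists did not pass camera (adjusted p = 0.094, 0.15 and 0.219), nor did any of the 3 with a filter at the median (0.473 each). Among them the chaperone gene CANX went from 183 to 390 without passing the test, and ATF3, a stress-induced transcription factor, fell from 27.5 to 1.65.

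Cytosolic ribosomal protein genes had a median log2 fold of 0.28 over 83 genes, none of which passed the test, and camera placed them higher than other genes (adjusted p = 0.000831, and 0.966 with an estimated correlation). With a filter at the median they did not pass camera (adjusted p = 0.378). Their median was nevertheless at percentile 0.14 among random lists matched on expression, and it turned to -0.10 and -0.19 after the 2 shifts.

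Epithelial markers were lower in the pools. Of 33 such markers 16 were tested. Of these, 10 fell and none rose, 15 were lower in both pools, and 11 fell when adjusted over the list alone (camera adjusted p = 0.000314, and 0.966 with an estimated correlation). The list median was at percentile 0.11 among matched lists and 4.89 when matched on the pool mean. With the transcript chosen without the vector value, the list median moved from -3.61 over 16 genes to -1.73 over 13 (camera adjusted p = 0.0061), and with a filter at the median the list did not pass camera (0.0758). Among genes above 0 in both pools, chosen after seeing the data, the list passed camera downward (9 genes, median -1.23, adjusted p = 0.000232). The vector excess bears on these 9 genes as well. EPCAM, an epithelial adhesion molecule, had a vector coverage of 66.3 and was listed at 0 in both pools, as were SPINT1 at 66.3, the keratin gene KRT19 at 17.4, CLDN7 at 12.5 and DSP at 11.3. SPINT2, an inhibitor of serine proteases, fell from 321 to 0.39 ± 0.12 (SD, n = 2). MUC1 fell from 59.3 to 2.86 ± 0.19 (SD, n = 2), but with the transcript chosen without the vector value its log2 fold was 0.57. Of the 10 genes that fell, 7 were listed at 0 in both pools and passed the filter only through their vector value, so their fall was fixed in advance.

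Mesenchymal markers did not pass camera as a list (22 genes, median log2 fold 0.25, camera adjusted p = 0.618), with 1 that rose, CDH2, and 5 that fell. TNC and TGFBI had vector values of 12.2 and 12.1 and were listed at 0 in both pools, and ACTA2 and MMP14 fell as well. The TGF-beta and SMAD list held SMAD7 and ENG among its 5 genes that fell and none that rose (27 genes, median 0.13, camera adjusted p = 0.847).

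Marker lists of other cell types and of the ovarian carcinoma lineage were compared as well. Of 12 endothelial markers 7 were tested and 6 fell (camera adjusted p = 0.00513, and 0.966 with an estimated correlation; percentile 8.75 among matched lists, 34 on the pool mean), with KDR at 167 and VWF at 36.6 in the vector library and both listed at 0 in the pools. Of 18 neural and germ line markers 11 were tested and 6 fell (camera adjusted p = 0.0419, and 0.966 with an estimated correlation; percentiles 54.9 and 16.5), and DAZL and DDX4, genes of germ cells, had vector values of 16.0 and 12.1 and were listed at 0 in the pools. This list did not pass camera with no filter (0.194), medians set equal (0.301), a pseudocount of 10 (0.062), the mean of transcripts (0.0787), after the 2 shifts (0.438 and 0.462) or among genes above 0 in both pools (0.904). LIN28A, which binds let-7 precursors, fell from 99.5 to 16.4 ± 1.64 (SD, n = 2). Of 17 immune markers 3 were tested and 2 fell, CD74 and CD3E. With no filter 13 were tested, with a median log2 fold of -1.95 (camera adjusted p = 0.000249). Epithelial markers gave a camera adjusted p of 0.000863 in that setting. Of 12 fibroblast markers, 2 fell, PDPN and DPT (camera adjusted p = 0.56), while DCN went from 144 to 450 ± 41.9 (SD, n = 2) and did not pass the test (limma adjusted p = 0.058). Of 15 ovarian carcinoma lineage markers 7 were tested and 5 fell (camera adjusted p = 0.0175, and 0.966 with an estimated correlation; percentiles 1.14 and 25.9), among them the oestrogen receptor gene ESR1, at 104 in the vector library and 0 in both pools.

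Genes of interferon response included MX1 and IRF7 among 6 that fell, with none that rose, and 18 of the 25 were lower in both pools (median -0.65, camera adjusted p = 0.0631). The interferon list passed camera downward with rows chosen without the vector value (adjusted p = 0.0152) and a pseudocount of 10 (0.0364). It did not with no filter (0.168), a filter at the median (0.657), medians set equal (0.11) or the mean of transcripts (0.159). Nor did it among genes above 0 in both pools (0.219) or after the 2 shifts (0.0952 and 0.0954). Replication-dependent histone genes had 13 that fell, such as HIST2H2BE from 209 to 2.92, and 1 that rose, HIST1H4H from 2.27 to 4.48 (39 genes, camera adjusted p = 0.0674). Of these 13, 6 were listed at 0 in both pools. The histone list passed camera with library medians set equal (adjusted p = 0.0335) and with the mean of transcripts (0.0329). It also passed with rows chosen without the vector value (0.0132) and among genes above 0 in both pools (0.02). It did not with no filter (0.82), a filter at the median (0.411) or after the 2 shifts (0.0809 and 0.0906). C2H2 zinc finger genes had 82 that fell and 11 that rose among 415 (median -0.06, camera adjusted p = 0.817), with ZNF25 and ZNF101 among those that rose, from 1.57 to 5.27 and from 0.864 to 4.10. Among the 28 p53 target genes, ZMAT3 rose from 0.99 to 3.31, and FAS and PMAIP1 fell (camera adjusted p = 0.0566). Of the 27 genes of hypoxia and glycolysis, NDRG1 and ADM fell, while 20 were higher in both pools (camera adjusted p = 0.0586). That list passed camera upward with no filter (adjusted p = 0.00412), medians set equal (0.02), a pseudocount of 10 (0.0364), the mean of transcripts (0.0253) and the first shift (0.0479). It did not with a filter at the median (0.473), among genes above 0 in both pools (0.166) or after the second shift (0.0537). The BCL2 family had 2 genes that fell of 16, PMAIP1 and BCL2L11 (adjusted p = 0.4), and the microRNA pathway 1 of 17, LIN28A (adjusted p = 0.0937). Stem cell and drug resistance genes had 6 that fell of 18, including PROM1, SOX9 and CD44, each listed at 0 in the pools (adjusted p = 0.458). WNT genes had 2 that fell of 18, TCF7 and DKK3 (adjusted p = 0.56), and early genes of ERK signalling 2 of 17, FOSL1 and EGR2 (adjusted p = 0.56), all by camera.

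Reported miR-181a targets did not pass camera as a list. Of 53 such genes 39 were tested. Among all 12552 tested genes 2725 fell and 126 rose. In the list 6 fell and none rose, over all genes and adjusted over the list alone, while 19 were higher and 15 lower in both pools (median log2 fold 0.13, camera adjusted p = 0.56). Of the 2725 genes, 1535 were at 0 in both pools and their fall was fixed by the filter, against 1 of the 6 in the list. The shares that fell can therefore not be set side by side. After the 2 shifts the median was -0.25 and -0.34, against -0.31 and -0.40 for all tested genes. Beside SMAD7, the genes that fell were CYLD, a deubiquitinase, from 43.5 to 3.31 ± 0.54 (SD, n = 2), BCL2L11, which encodes the apoptosis activator BIM, from 9.54 to 0.35 ± 0.24 (SD, n = 2), LIF, PLAG1 and GRIA2. PLAG1, a zinc finger transcription factor, went from 3.86 to 2.16 ± 0.08 (SD, n = 2), and GRIA2 had 39.5 in the vector library and was listed at 0 in both pools.

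Genes with a miR-181a site in the 3 prime UTR were compared with the rest to ask for a wider effect of the seed. A site of any type (TGAATGTA, TGAATGT or GAATGTA) was found in 3234 of the tested genes and none in 9038, with median log2 folds of 0.08 and 0.07 (camera p = 0.525, and p = 0.94 with an estimated correlation). The 825 genes with TGAATGTA, the longest match, had a median of 0.02 and did not stand apart either. In pool 1 their median differed from that of genes without a site by -0.02 and in pool 2 by -0.04. Between genes with TGAATGT and the rest the medians differed by -0.03, which lay at percentile 7.79 among 2336 other 7-mers of like frequency (12.5 in pool 1 and 14.9 in pool 2). For GAATGTA the difference was 0.03, at percentile 61.7. Neither genes with any site nor those with TGAATGTA passed camera. In alternatives chosen after seeing the data, TGAATGT was at percentile 1.69 among genes above 0 in both pools (1.02 in pool 1 and 8.10 in pool 2), and at 5.42 among 7-mers of the same base composition (14.8 in pool 1 and 2.96 in pool 2).

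The folds of the 2 pools against the shared vector library had a correlation of 0.989 across genes, which are not independent replicates, and a covariance of 3.67. Unchanged pools sharing 1 vector library gave a correlation of 0.50 and a covariance of 0.04, 0.987 and 3.00 when the vector excess was added, and 0.988 and 3.56 in the mixed libraries. The single vector library could not be split, so part of what remains may come from that library.

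Pool 2 differed from pool 1 by at least 1 log2 unit in 22 genes that were higher and 125 that were lower, with 1 library each and no test. NTS, which encodes the peptide neurotensin, had a coverage of 2.93 in pool 1 and 41.5 in pool 2, against 19.8 in the vector library. CBLN2, HSPB1, which encodes a small heat shock protein, ZP3 and VCAN were the next highest in pool 2, with VCAN at 1.43 and 9.47. CD70, a ligand of the tumour necrosis factor family, had 18.4 in pool 1 and 2.67 in pool 2, and DNAL1, PCSK1N, C16orf74 and CHAC1 were the next lowest. The median log2 difference over all tested genes was -0.27, and relative to it 46 genes were higher and 25 lower in pool 2.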

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

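No paired analysis was possible because the vector has 1 library and the groups share fewer than 2 replicate numbers. With no counts in the table, depth sets no stated limit, and 1 residual degree of freedom limits the test. Where no cause is named below, the cause was not tested. Of 3053 comparisons of 236 named genes with their alternatives, 3043 kept the sign of the log2 fold, but many of these could not change it. The filters, the variance models and the restriction to genes above 0 leave the fold of a gene as it is. A pseudocount, or leaving out 1 pool, cannot turn the sign where both pools lie on the same side of the vector library. SMAD7 passed the test in 12 of 12 alternatives with a test (log2 fold -5.01 to -2.54, highest adjusted p 0.017), CDH2 in 8 (1.70 to 2.94, highest 0.0774), SPOCK2 in 7 (3.25 to 4.44, highest 0.102) and CENPF in 8 (1.03 to 1.91, highest 0.0757). Genes that rose numbered 278 with no filter, 402 with a filter at the median, 43 with robust eBayes, 6355 with library medians set equal, 447 among genes above 0 in both pools, and 1039 and 710 after the shift by the median ratio of genes above 50, by the mean of all libraries and by the pool mean. Of the 126 that rose, those kept were 92 with no filter, 8 with the median filter, 40 with robust eBayes, 122 with medians set equal, 80 among genes above 0 in both pools, and 45 and 35 after the shifts. Without a variance trend 45 were kept, and with pseudocounts of 0.1 and 10 those kept were 69 and 73. Genes that fell numbered 5626 with no filter, 1476 with the median filter, and 5390 and 5784 after these 2 shifts. By the size rule, 1711 genes were higher at 1.5-fold, 2188 with medians set equal, 506 and 63 with pseudocounts of 0.1 and 10, and 86 and 61 after the shifts. Lower genes numbered 5718 with no filter, 1428 with the median filter, 2282 with a pseudocount of 10, 1697 among genes above 0 in both pools and 226 where the vector excess passed the 99th percentile of silent transcripts. Leaving out 1 pool gave 356 to 1305 genes higher, the latter without pool 2, and the median fold was 0.24 in pool 1 and -0.12 in pool 2. Lists past camera numbered 0 with an estimated correlation, 1 with the median filter, 4 among genes above 0 in both pools and 7 after the second shift, against 9. Between pools, the alternatives gave 71 higher and 1760 lower at 1.5-fold, 9 and 58 with the median filter, 53 and 19 with medians set equal, 138 and 400 with a pseudocount of 0.1, 1 and 7 with a pseudocount of 10, 55 and 18 after the first shift, 56 and 18 after the second, and 34 higher with no filter. For seed sites, the difference in median was 0.0017 to 0.0038 for any site and -0.0443 to -0.0238 for the 8mer with 1 pool left out. Its sign changed without a call for any site with the median filter (-0.0304), a pseudocount of 10 (-0.00336) and genes above 0 in both pools (-0.0375), and for the 8mer with no filter (0.0752). The percentile of TGAATGT was 5.42 among 7-mers of the same composition, 5.74 with rows chosen without the vector value and 1.69 among genes above 0 in both pools, and 12.5 to 14.9 with 1 pool left out. Direction reversed for 5 named genes and 1 list that passed the test in one of the 2 settings. These were MUC1 (0.57), ZNF260 (0.40) and ZNF611 (0.18) with rows chosen without the vector value, ZNF674 (0.0132) with medians set equal, ZNF799 (-0.00902) after the second shift, and neural and germ line markers among genes above 0 in both pools (camera adjusted p = 0.904). The other 5 sign changes were in 4 genes past the test in neither setting, C16orf74 (2), CDC25A, NTS and PCSK1N, and the median of 14 of 23 lists changed sign in at least 1 alternative, 5 of them without the shifts. Relative to all tested genes the median of 8 lists changed sign, among them reported miR-181a targets (-0.0804 with the median filter). Correlation of the pools without 1 pool could not be computed.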

Other observations

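The tests of row agreement, of the added vector amount, of equal values, of SMAD7, of library scale and of single transcripts, and the genes picked in the next paragraph, were chosen after the result was seen, and the tests of sites in silent genes and in zinc finger genes before.

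Among genes with 2 or more transcripts of distinct vector value, 21 were lower in every transcript and exceeded the pools by more than the 99th percentile of the vector values of silent transcripts. They include SPINT2, the death receptor FAS, with 223 in the vector library against 0.63 ± 0.28 (SD, n = 2), the adhesion molecule CADM1, the sulfatase SULF2, the endothelin receptor EDNRA and the kinase PDPK1, with 373 against 8.79 ± 2.85 (SD, n = 2). Unchanged libraries with the vector excess added gave 12 to 30 such genes and mixed libraries 9 to 23. Without the limit on the excess, 420 genes were lower in every transcript, above the 278 to 342 and 289 to 367 of these simulations, which draw each transcript separately.

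Values in the vector library for transcripts at 0 in both pools are a pattern that limits the falls. RNA from another cell type would be read alike by the transcripts of 1 gene, but among 571 silent genes whose 2 transcripts averaged 0.5 to 20, 1 was at 0 and the other above 0 in 37.8%, against 0.5% in pool 1 at the same average, which argues against that source. Silencing by miR-181a would leave more sites in genes with a vector value, and 21.6% of 3826 such genes held a site against 20.6% of 1805 genes at 0 in all 3 libraries (odds ratio 1.06, Fisher's exact 95% interval 0.92 to 1.22), which argues against direct silencing as the main cause. An amount unrelated to the gene, added to the vector values, predicted 13.6% to 15.4% of transcripts of pool mean 1 to 10 with a vector value over 4 times that mean, and 14.3% were observed. The 1374 lower genes of pool mean 1 or more lay outside its 1679 to 1829. That simulation set no difference in scale between the vector library and the pools, so this count cannot decide, and an added amount stays open. Mixed libraries gave 1430 to 1552 lower genes of pool mean 1 or more, also above the 1374 observed. Coverage of other transcripts mixed in could leave equal values in unrelated genes. These were found in 8.26% of 109 silent transcripts with a vector value of at least 100 against 0.52% in pool 1, but these are 9 transcripts, and whether any step mixed them stays open.

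The fall of SMAD7 and the excess of the vector library were not told apart. The limit set for excluding the excess could be met only by a value above 727, the highest vector value of a silent transcript. That test could therefore hardly exclude it. A vector value as large as its excess occurred in 2.38% of silent transcripts, and SMAD7 has 1 transcript, so no second reading decides. A reported target of miR-181a would also be lower, which stays open as a biological explanation.

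Genes at least 1 log2 unit higher in both pools stand open between a change in the cells and a technical source. A difference in library scale would be removed by the shift, but 86 remained after each pool was shifted by 0.55 or 0.21, the median ratio of genes with a mean over the 3 libraries above 50, and 61 with 0.64 or 0.30 from genes with a pool mean above 50, against 0 to 3 in unchanged libraries, so scale does not account for these and may account for others. Readings of single transcripts would extend less often to every transcript of a gene, and 46 of 87 genes with distinct vector values were higher in every transcript. The share expected in unchanged libraries was simulated for lower genes only, so 46 of 87 has no such share beside it and does not decide. Dilution of vector values by those of other transcripts, in shares that differ between transcripts, and differences between the cultures other than miR-181a were not tested and stay open.

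Zinc finger genes of the C2H2 type often carry miR-181a seed matches in the coding sequence, which might lower them. The 183 such genes with 3 or more matches had a median log2 fold of -0.20 and the 149 with none a median of 0.00, a difference of -0.20 (two-sided permutation test with 100000 resamples, p = 0.23). The difference did not pass 0.05, and a p above the threshold does not exclude an effect of this size.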
